A study of Mus musculus with 2 samples.

How the data were processed

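Open chromatin was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in intestine of mouse embryos (strain B6NCrl per the labels) at embryonic day 16.5. Per the labels, there were 2 libraries, biological replicates 1 and 2 of 1 group, each from tissue pooled over embryos of both sexes. Replicate 2 came from 41 embryos and the number for replicate 1 was not stated. No treatment, other age or other tissue was part of the series, so the comparisons made were between the replicates, between the deposited peak lists, and between gene groups and sequence motifs within the lists.

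The starting point was 12 peak lists on the mm10 build that the authors deposited, with no read counts. Per the deposited notes, the lists came from filtered alignments, 3 from each library alone and 6 from both libraries together, and all except the ranked lists were made with 1 further set of genomic regions whose content was not used here. The aligner, the peak caller, their versions, any shift of reads for the transposase and any control were not given in the sources used here. Each entry of a list is a summit with its enclosing interval. The signal value that the authors deposited for each summit was read as an enrichment ratio over the caller's background, from the column order of the format and the values, since neither the caller nor a control was stated. The authors also deposited a −log10 p and a −log10 q for each summit, and in the ranked lists a −log10 of the irreproducible discovery rate (IDR), a measure of how poorly a summit ranks across a pair of call sets. The IDR lists keep summits that pass an IDR threshold. Which pair stood behind each of the pooled ranked lists was read from the values. The inputs behind the conservative list equalled the own ranked summits of the 2 libraries, and those behind the other pooled IDR list, here called optimal, equalled neither library's. The replicated and pseudoreplicated lists are looser and hold about as many summits as the ranked lists.

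Sequencing depth per library was unknown, because the lists hold no counts, so no counting interval was put on any signal value. The signal value is relative to the background of its own list, and a ratio of signal values between libraries describes the lists and not a measured change in accessibility. With 1 library on each side, no test between the libraries was possible. Means over the libraries are given with the SD (n = 2). All p-values below are over regions or genes, which are not replicate samples, and they say nothing about the spread between embryos.

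Summits whose intervals shared at least 1 bp were merged into regions, and a region took the position and signal value of its strongest summit. Chromosomes 1 to 19, X and Y were used. The conservative list (44356 regions) served for all gene and motif results. The reference was the GRCm38 genome with GENCODE release M21 (21938 protein-coding genes, 132721 distinct start sites of all genes), and no summit on these chromosomes lay past a chromosome end. A region was called promoter when its summit lay within 1000 bp of any annotated start site, otherwise exon, intron or intergenic, and distal regions were those that were not promoter regions. Coordinates are 1-based on mm10.

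Overlap of the replicates was set against 100 random placements of the regions on their own chromosomes (one-sided permutation p, smallest possible 0.0099). The genomic distribution was set against 100 such placements (two-sided, smallest possible p 0.0198). A gene had an accessible promoter when a region overlapped the window of 1000 bp around any of its start sites. The 22 gene lists held 405 entries, all matched to the annotation, 1 of them by an older symbol, and 1 gene, Hoxb5, stood in 2 lists. Promoter shares were compared with all other protein-coding genes by two-sided Fisher's exact tests. Distal regions were assigned to the nearest protein-coding start site within 100000 bp, and the mean per list gene was compared with 10000 random gene lists of the same size, drawn within 10 bins of the length of genome that could be assigned to each gene (two-sided permutation p, smallest possible 0.0002). For 20 motif consensus sequences, the share of distal regions with a match on either strand within 100 bp of the summit was compared with windows of equal width centred 600 bp to either side. The log2 ratio used 0.5 added to each count and a 95% interval from 1000 bootstrap draws of regions, and the p came from an exact McNemar test against the upstream window. Benjamini-Hochberg adjustment was made within the 22 lists or the 20 motifs, with a threshold of 0.05. The log2 ratio of replicate 1 to replicate 2 signal values, centred on its median over shared regions, was summarised per gene list and ranked among 10000 random sets of regions matched on mean signal value.

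The genes named were, per list, the 3 with the strongest promoter region by the mean signal value of the libraries and the first 2 in list order without a promoter region, and in addition the 10 strongest distal regions, the 5 regions with the largest ratio in each direction between the libraries, and the Hox clusters. Gene lists, motifs, tests, this rule and every alternative except 1 were fixed before the data were examined. The exception, matching of genes on GC content, was added after the distal results were seen. The other alternatives changed the peak list, the overlap required, a stricter −log10 q of at least 10, the promoter window, the assignment distance, the matching, the motif window and background, the measure of strength, and left out each replicate in turn by using the other library's own list.

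The procedures were tested on simulated data. With random regions, 0 of the 22 lists passed either list test, and 1 of 1 planted list was recovered by each. A motif planted in 5% of 20000 windows of random sequence gave an excess of 4.98%, with 0 of the 19 other motifs past the threshold. The random regions lacked the concentration of the real regions at gene starts, and the random sequence lacked their base composition. These runs therefore do not show how often false calls arise in the real lists. A list with ratios shifted by 0.3 on the log2 scale was recovered among 27108 regions, with 1 of the 21 other lists also outside the central 95%. Further tests, chosen after the results were seen, are given at the end. Sequence copies were sought with blastn 2.17.0. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.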

Results

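Accessible chromatin was mapped in intestine of mouse embryos at day 16.5 from 2 ATAC-seq libraries, biological replicates made from separately labelled pools of embryos. The replicate 1 list held 83814 summits in 34534 regions, which covered 30.3 Mb. The replicate 2 list held 76146 summits in 31145 regions over 27.7 Mb. The mean over the libraries was 32840 ± 2396 regions (SD, n = 2), with a median region width of 852 ± 12 bp and a median signal value of 7.40 ± 0.00999. The conservative list, called on both libraries together and thresholded on the 2 true replicates, held 109550 summits in 44356 regions over 39.8 Mb. The depth behind these lists was unknown.

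Most accessible regions were found in both pools, and regions at promoters made up a larger part of the shared regions than of those called in a single library. Of the replicate 1 regions, 27406 of 34534 (79.4%) shared at least 1 bp with a replicate 2 region, and 27412 of 31145 replicate 2 regions (88.0%) shared with replicate 1. Random placement gave 2.22% and 2.47%, so the overlap was 35.8-fold and 35.6-fold over chance (one-sided permutation p = 0.0099 in both directions, the smallest that 100 placements allow). Such placement ignores that accessible regions concentrate at gene starts. The fold and p therefore show an excess over uniform placement and do not measure how closely the replicates match. Promoter regions were 50.4% of the shared regions, 19.2% of the 7128 regions only in the replicate 1 list and 17.1% of the 3733 only in the replicate 2 list. The median signal value was 5.43 in the regions only in replicate 1 against 8.24 in its shared regions, and 5.35 against 7.85 in replicate 2. Of the regions only in replicate 1, 95% were present in the ranked list of replicate 2 before thresholding, and 96.2% the other way round.

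Among 27108 joint regions called in both libraries, log2 signal values correlated across regions with Pearson's r = 0.933 and Spearman's rho = 0.926, where regions are not independent replicates. The SD of the log2 ratio was 0.20, and 99% of the regions lay within 1.5-fold after centring. The promoter region of the intestinal fatty acid-binding protein gene Fabp2 was among the 5 regions with the largest ratio towards replicate 1. The region on chromosome 3 (122894860 to 122895704), with the summit 269 bp from the start site in a stretch that also carries the antisense gene 4933405D12Rik, had a signal value of 10.2 in replicate 1 and 5.43 in replicate 2, a centred log2 ratio of 0.86. The other regions with the largest ratios towards replicate 1 were nearest to Npffr2 (0.97, intergenic), Atg10 (0.80, intron), Kcnab2 (0.78, intron) and Nme9 (0.77, in an exon of Armc8). Towards replicate 2, the largest ratio belonged to a region on chromosome 11 (65341398 to 65342348) in an intron of the long non-coding RNA gene Gm12295, 71896 bp from the start site of Myocd, the smooth muscle co-activator of SRF. It had a signal value of 4.95 in replicate 1 and 9.78 in replicate 2 (centred log2 ratio −1.04). Regions nearest to Spin2c (−0.99, promoter), Dock9 (−0.97, intron), Hpcal1 (−0.94, at a start site of the pseudogene Gm49329) and F2rl2 (−0.91, in an intron of Iqgap2) followed.

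**Figure D1:**
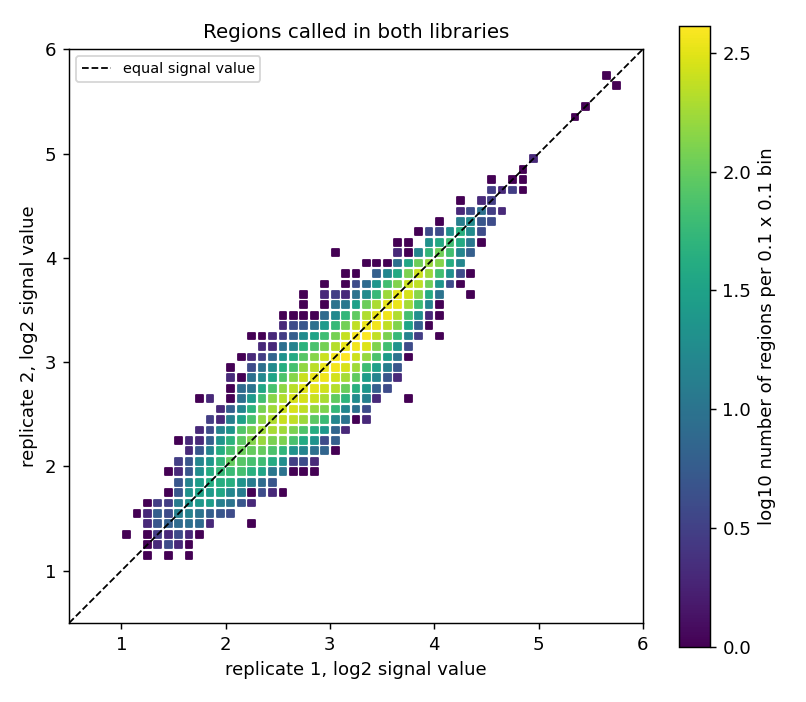
Log2 signal value of replicate 2 against replicate 1 for the 27108 joint regions called in both libraries, in bins of 0.1 by 0.1 coloured by the log10 number of regions. The dashed line marks equal signal values, and Pearson's r across regions was 0.933.

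By signal value, the gene lists lay within the central 95% of random sets of regions, some of them near its edge. For the 22 lists, the median centred log2 ratio of replicate 1 to replicate 2 ranged from −0.08 for 7 regions at erythroid genes to 0.13 for 8 regions at pancreas genes. The medians were −0.04 over 88 regions of gut epithelial transcription factors, −0.03 over 63 regions of enterocyte genes, 0.03 over 60 regions of stem cell and Wnt target genes, −0.04 over 42 regions of mesenchyme genes and 0.00 over 22 regions of enteric nervous system genes. Of the 22 lists, 0 lay outside the central 95% of 10000 random sets matched on mean signal value, where chance gives 1.1. Nearest to its edges were cell cycle genes (percentile 97.47, just inside), pancreas genes (96.6) and gut epithelial transcription factors (3.89). This is a description of these 2 libraries and not a test between them. With −log10 p in place of the signal value, 4 lists lay outside, with gut epithelial transcription factors (percentile 1.08) and enterocyte genes (0.390) on the side of replicate 2 and stem cell and Wnt target genes (98.9) and cell cycle genes (98.2) on the side of replicate 1.

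The deposited lists overlapped in large part. Of the conservative regions, 89.2% overlapped the optimal list and 99.8% the replicated list, while 72.9% overlapped the replicate 1 list and 67.1% the replicate 2 list. Of the optimal regions, 87.2% overlapped the conservative list. Of the replicate 1 and replicate 2 regions, 94.7% and 96.7% were in the conservative list. The looser replicated list was larger, with 95905 regions, of which 46.2% overlapped a conservative region.

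Accessible regions concentrated at gene starts. Promoter regions made up 16790 of the 44356 conservative regions (37.9%), against 6.35% of randomly placed regions, and 45.2% ± 1.74 (SD, n = 2) in the lists of the single libraries. Introns held 14438 regions (32.6% against 40.2% by chance), intergenic sequence 11734 (26.5% against 50%) and exons 1394 (3.14% against 3.39%). Two-sided permutation p was 0.0198 for promoter, intron and intergenic regions, the smallest that 100 placements allow, and 0.0396 for exons. The median signal value was 8.52 in promoter regions and 5.65 in intronic regions. Chromosome 11 had the densest cover, with 24.5 regions per Mb, while the X chromosome had 5.52 and the Y chromosome 0.120. In the replicated list the promoter share was lower (24.7%) and the exon share was above chance (3.97%, permutation p = 0.0198 for both against placement), and with a promoter window of 500 bp the exon share of 3.82% was not past the threshold (permutation p = 0.535).

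Promoters of intestinal epithelial regulators and structural genes were accessible more often than those of other genes. A conservative region lay within 1000 bp of a start site in 21 of 22 gut epithelial transcription factors (95.5%), all 20 epithelial junction and structure genes and 15 of 16 stem cell and Wnt target genes (93.8%), against 64.6% of other protein-coding genes. All 12 cell cycle genes and all 18 housekeeping genes were also accessible. Of all 21938 protein-coding genes, 14177 (64.6%) had such a region, and of 1135 olfactory receptor genes 9 (0.793%) did. Adjusted p, from two-sided Fisher's exact tests, was 0.00163 for junction genes, 0.00300 for housekeeping genes, 0.00467 for the transcription factors, 0.0313 for cell cycle genes and 0.0374 for stem cell and Wnt target genes. In the lists of the single libraries the transcription factor share was 93.2% ± 3.21, the junction share 90% ± 7.07 and the stem cell and Wnt share 87.5% in both libraries (SD, n = 2).

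Among the transcription factors the strongest promoter region was at Klf5 (ENSMUSG00000005148.8), a zinc finger factor of epithelial progenitors. It spanned 99298185 to 99299430 on chromosome 14, with the summit in intergenic sequence 88 bp from the start site, and had a signal value of 12.5 ± 0.139 (SD, n = 2). The forward strand around the summit reads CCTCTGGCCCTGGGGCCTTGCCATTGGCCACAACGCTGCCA. Hnf4g (ENSMUSG00000017688.14), a nuclear receptor of enterocytes, followed with 9.88 ± 1.06 at 3633561 to 3634496 on chromosome 3, at an internal start site within an intron, and Onecut2 with 9.64 ± 0.677. Cdx1, the homeobox gene of the posterior gut, was the single factor of the 22 without a region, and it had one in the looser replicated list. Among junction and structure genes the strongest were the tetraspanin gene Tspan8 (11.4 ± 0.743), Phgr1 (10.1 ± 0.127) and Cdh1 (8.99 ± 0.225), which encodes E-cadherin. The Cdh1 region (ENSMUSG00000000303.12) spanned 106603110 to 106603906 on chromosome 8, with the summit in the untranslated part of an exon 11 bp from the start site. The Wnt-regulated receptor gene Ephb3 led the stem cell list with 12.6 ± 0.30, and its summit sequence, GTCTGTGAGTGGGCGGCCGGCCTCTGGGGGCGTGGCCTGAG on chromosome 16 (summit 21204692), held a match to the KLF/SP consensus. Lrig1 (11.7 ± 0.110) and Rnf43 (10.3 ± 3.29), both regulators of crypt signalling, followed, and the Wnt antagonist gene Notum had no region. Rnf43 had a signal value of 12.6 in replicate 1 and 7.95 in replicate 2.

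In the conservative list, promoters of genes for absorption, secretion, the other compartments of the gut wall and the pancreas were neither above nor below other genes past the threshold. Enterocyte digestion and absorption genes had 18 of 24 (75.0%, adjusted p = 0.465, Fisher's exact test), with Mttp, which loads lipid onto apolipoprotein B, at 13.6 ± 0.0163 (SD, n = 2). Dgat1, an enzyme of triglyceride synthesis, had 10.5 ± 0.339 and the glucose transporter gene Slc2a2 had 9.51 ± 0.954, while Apoa1 and Fabp1 had no region. The Mttp region (ENSMUSG00000028158.14) spanned 138143222 to 138144254 on chromosome 3, with the summit in a non-coding exon. Secretory lineage genes had 13 of 27 (48.1%, adjusted exact p = 0.154), with the granin gene Chgb at 15 ± 1.11, where a match to the REST consensus lay at the summit, and no region at the endocrine regulators Neurog3 and Neurod1. Mesenchyme genes had 24 of 29 (adjusted exact p = 0.0792), with Gli3 at 10.2 ± 0.851. Smooth muscle and interstitial cell of Cajal genes had 15 of 17 (adjusted exact p = 0.0746), with Etv1 at 11.6 ± 0.348 and Mylk at 10.9 ± 1.20, and no region at Actg2 or Ano1. Enteric nervous system genes had 12 of 22 (adjusted exact p = 0.465), with Elavl4 at 11 ± 2.46 and the receptor gene Ret at 8.80 ± 0.0482, and no region at Gfra1 or Phox2b. Endothelial genes had 13 of 19 (adjusted exact p = 0.896), with no region at Pecam1 or Cdh5. Erythroid genes had 8 of 12 and mesothelial genes 6 of 9 (both adjusted exact p = 1), with Nfe2 at 12.6 ± 0.155 and Upk3b at 7.8 ± 0.405, and pancreas genes had 7 of 13 (adjusted exact p = 0.465), with Mafa at 14 ± 1.54. In the own lists of replicate 1 and replicate 2 the share was 38.5% and 30.8% for pancreas genes, 42.1% and 36.8% for endothelial genes, and 41.7% in both for erythroid genes. In the replicate 1 list alone the secretory lineage genes fell below other genes (33.3%, adjusted exact p = 0.0120), and in the replicate 2 list alone the enteric nervous system genes did (31.8%, adjusted exact p = 0.0322). Above other genes were mesenchyme genes in the optimal list (89.7%, adjusted exact p = 0.0102) and the replicated list (96.6%, 0.00852), enterocyte genes in the optimal list (87.5%, 0.0346), and smooth muscle genes in the replicated list (100%, 0.0168) and with a 2 kb window (94.1%, 0.0434).

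Germ cell, immune, heart and skeletal muscle, hepatocyte, lung and kidney, and stomach genes had accessible promoters less often than other genes, while pancreas and forebrain genes were not past the threshold. The count was 2 of 16 germ cell genes (12.5%, adjusted p = 0.000567, Fisher's exact test), 4 of 18 immune cell genes (22.2%) and 3 of 16 heart and skeletal muscle genes (18.8%, both adjusted p = 0.00163), 4 of 14 hepatocyte genes (28.6%, adjusted p = 0.0276), 4 of 13 lung and kidney genes (30.8%, adjusted p = 0.0374) and 3 of 11 stomach genes (27.3%, adjusted p = 0.0427). Forebrain and glial genes, with 9 of 18, were not past the threshold (adjusted exact p = 0.303), with Lhx2 at 8.75 ± 0.432 and no region at Neurod6 or Emx2. The 2 germ cell genes with a region were Dazl (10.4 ± 1.20, SD, n = 2) and Gdf9 (8.78 ± 0.702), and Ddx4 and Sycp1 had none. Immune genes with a region included Runx1 (8.71 ± 0.773) and Ikzf1 (6.10 ± 0.314), while the pan-leukocyte gene Ptprc and the myeloid factor gene Spi1 had none. Ryr2, the cardiac calcium release channel gene (10.0 ± 3.17), and Ckm (6.63 ± 1.34) had a region, and the heart genes Myh6 and Nkx2-5 had none. The plasma protein genes Apoh (12.2 ± 0.394) and Proz (10.8 ± 0.159) had a region, with an HNF4 consensus match at the Proz summit, and Alb and Afp had none. The gastric proton pump gene Atp4a (11.5 ± 0.653) had a region, and Gkn2 and Tff1 had none. Nphs1 (8.98 ± 1.22) had a region, and the lung genes Nkx2-1 and Sftpc had none.

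Several of these list calls depended on which genes they were set against. Against random genes matched on the CpG content of the promoter, the calls ended (adjusted permutation p) for stem cell and Wnt target genes (0.933), cell cycle genes (0.933), housekeeping genes (0.0651), immune genes (0.887), hepatocyte genes (0.887), stomach genes (1) and lung and kidney genes (0.136). In the same comparison enterocyte genes were above matched genes (75.0% against 43.6%, adjusted permutation p = 0.00440), as were smooth muscle genes (88.2% against 60.4%) and erythroid genes (66.7% against 30.1%, both adjusted permutation p = 0.0335), and forebrain genes were below (50% against 74.9%, adjusted permutation p = 0.0335). Gut epithelial transcription factors (95.5% against 63.1%) and junction genes (100% against 59.6%) stayed above, and germ cell genes (12.5% against 64.2%) and heart and skeletal muscle genes (18.8% against 46.0%) below. In the replicate 1 list alone the calls for stem cell and Wnt target genes (adjusted exact p = 0.0698), hepatocyte genes (0.0897), stomach genes (0.0559) and lung and kidney genes (0.0698) were lost, and in the replicate 2 list alone that for lung and kidney genes was lost (0.0722). The shares in the replicate 1 list were 87.5%, 35.7%, 27.3% and 30.8% in that order, against 93.8%, 28.6%, 27.3% and 30.8% in the conservative list. With only the 5' end of each gene counted, the calls for gut epithelial transcription factors (81.8%, adjusted exact p = 0.0814), stem cell and Wnt target genes (87.5%, 0.0685) and hepatocyte genes (28.6%, 0.0505) also ended. The hepatocyte call was lost in 6 of 9 alternatives, among them the optimal list (0.0712) and a 2 kb window (0.0502). The heart and skeletal muscle call was lost in the replicated list (50%, adjusted exact p = 0.159) and with a 2 kb window (37.5%, 0.0514). In the looser replicated list the germ cell and immune lists were the 2 that remained below.

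**Figure D2:**
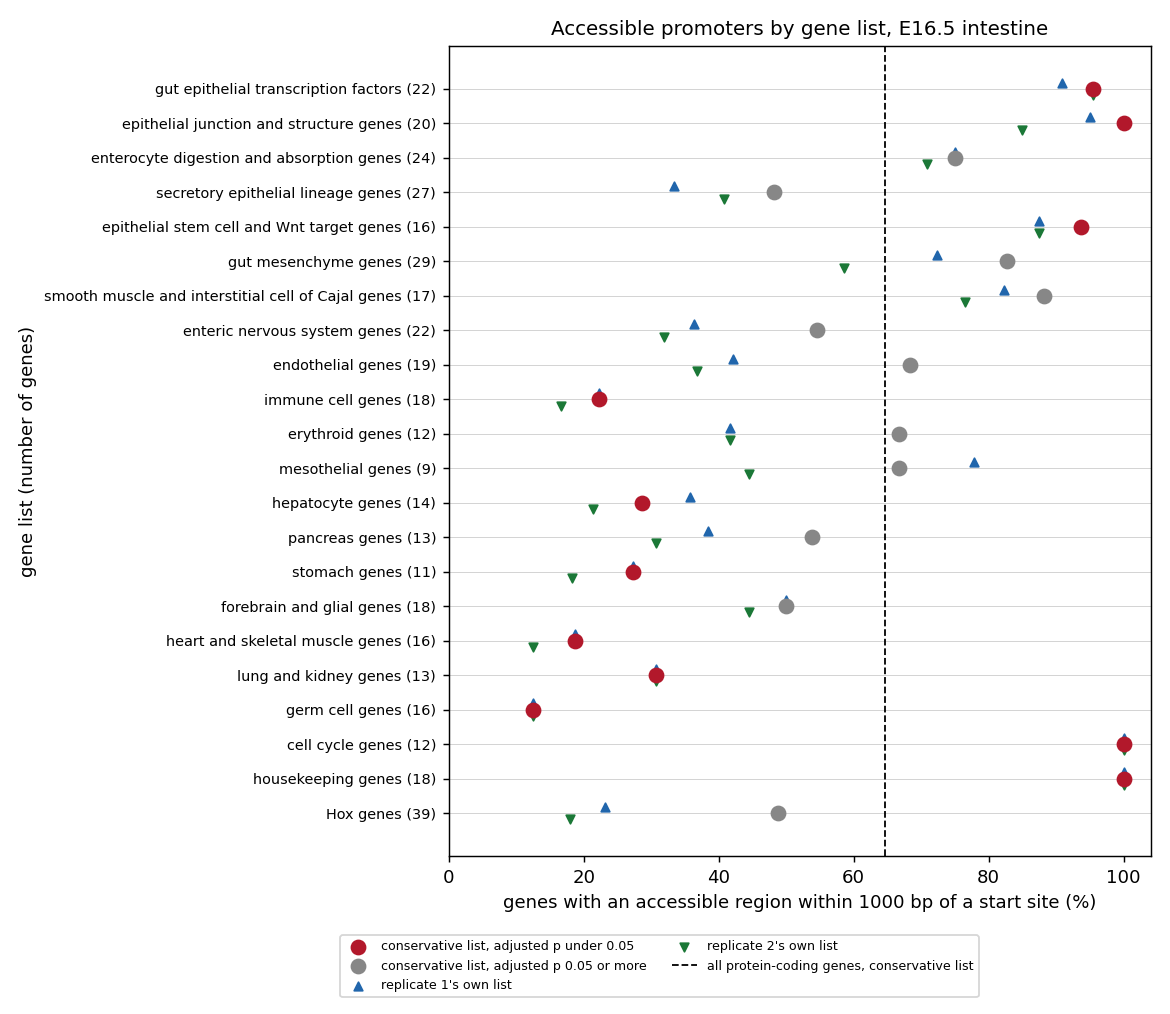
Percent of genes with an accessible region within 1000 bp of a start site for the 22 gene lists, in the conservative list (circles, red when the adjusted p was under 0.05) and in the own lists of replicate 1 and replicate 2 (triangles). The dashed line marks the 64.6% of all protein-coding genes in the conservative list, with 5 lists above and 6 below other genes.

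Hox genes, which pattern the gut along its length, were accessible at 19 of 39 promoters (48.7%, adjusted p = 0.0746, Fisher's exact test). In the Hoxa cluster on chromosome 6, 6 of 11 genes had a region (Hoxa1, Hoxa3, Hoxa4, Hoxa5, Hoxa7 and Hoxa10), and in the Hoxd cluster on chromosome 2, 6 of 9 (Hoxd1, Hoxd3, Hoxd4, Hoxd8, Hoxd10 and Hoxd13). In the Hoxb cluster on chromosome 11 the count was 3 of 10 (Hoxb3, Hoxb4 and Hoxb9), and in the Hoxc cluster on chromosome 15 it was 4 of 9 (Hoxc4, Hoxc5, Hoxc6 and Hoxc13). The Hoxa cluster held 11 regions and the Hoxd cluster 9, with 3 in the Hoxb and 4 in the Hoxc cluster. The strongest promoter regions were at Hoxd1 (6.17 ± 0.961, SD, n = 2), Hoxa1 (5.98 in replicate 1 and 6.04 in replicate 2) and Hoxb3 (5.59 ± 0.307). The Hoxb3 summit on chromosome 11 (96341206, intronic) read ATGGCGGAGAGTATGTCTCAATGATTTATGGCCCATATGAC, with a match to the CDX consensus. In the own lists of the libraries the share was 23.1% in replicate 1 and 17.9% in replicate 2, both below other genes (adjusted p = 3.04e-05 and 3.60e-06, Fisher's exact test). The conservative list's 48.7% was also below random genes matched on CpG content (84.7%, adjusted permutation p = 0.00110). All of these tests count the Hox genes as independent, although they lie side by side in clusters. The p-values of this list can therefore be too small.

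Relative to matched genes, the ratio of distal accessible regions was highest for 3 of the 5 epithelial lists, namely junction, transcription factor and enterocyte genes. Gut epithelial transcription factors had a mean of 5.05 distal regions per gene, against 1.64 ± 0.490 in random lists matched on assignable territory (mean ± SD over draws), a ratio of 3.08. The ratio was 4.26 for junction and structure genes, 2.86 for enterocyte genes and 2.04 for stem cell and Wnt target genes. Hnf4g, Tspan8 and Cdh1 each had 7 such regions, Lrig1 had 8, Klf5 and Slc2a2 had 5, and Apoa1 and Fabp1, which had no promoter region, had 3 each. Onecut2, Phgr1 and Dgat1 had 1 each, Ephb3 and Cdx1 had 2, Mttp and Rnf43 had 4, and Notum had 0. Housekeeping genes had a ratio of 2.42, above that of the stem cell list, and the secretory epithelial list had 1.04.

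Of 27566 distal regions, 23807 (86.4%) lay within 100000 bp of a protein-coding start site and were assigned to it. The adjusted permutation p was 0.00147 for each of the transcription factor, junction and enterocyte lists, whose raw p of 0.0002 is the smallest that 10000 random lists allow. It was 0.0473 for stem cell and Wnt target genes and 0.0475 for housekeeping genes. Of the 22 lists, 5 were above matched genes and 0 below. In the own lists of the libraries the ratio was 3.35 ± 0.132 for the transcription factors, 4.37 ± 0.224 for junction genes, 3.18 ± 0.365 for enterocyte genes and 2.46 ± 0.134 for stem cell genes (SD, n = 2). The ratios of the other compartments of the gut wall were not past the threshold. They were 1.43 for smooth muscle and interstitial cell of Cajal genes (adjusted permutation p = 0.837), 0.813 for mesenchyme, 0.828 for enteric nervous system, 1.1 for endothelial and 1.04 for secretory lineage genes (all adjusted permutation p = 1). Among genes of other organs the ratio ranged from 0.706 for stomach genes to 1.43 for hepatocyte genes, none past the threshold. In the replicate 2 list alone heart and skeletal muscle genes were at 0.463, from 0.914, and in the replicate 1 list alone pancreas genes were at 0.671, from 1.27. The stem cell call ended with matching on GC content in addition (ratio 1.31, adjusted permutation p = 0.497), with assignment within 50 kb (1.77, p = 0.127) and with a −log10 q of at least 10 (2.02, p = 0.0528). The housekeeping call ended in 7 of 9 alternatives, including the replicate 1 list alone (2.28, adjusted permutation p = 0.133) and GC matching (2.01, p = 0.125).

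**Figure D3:**
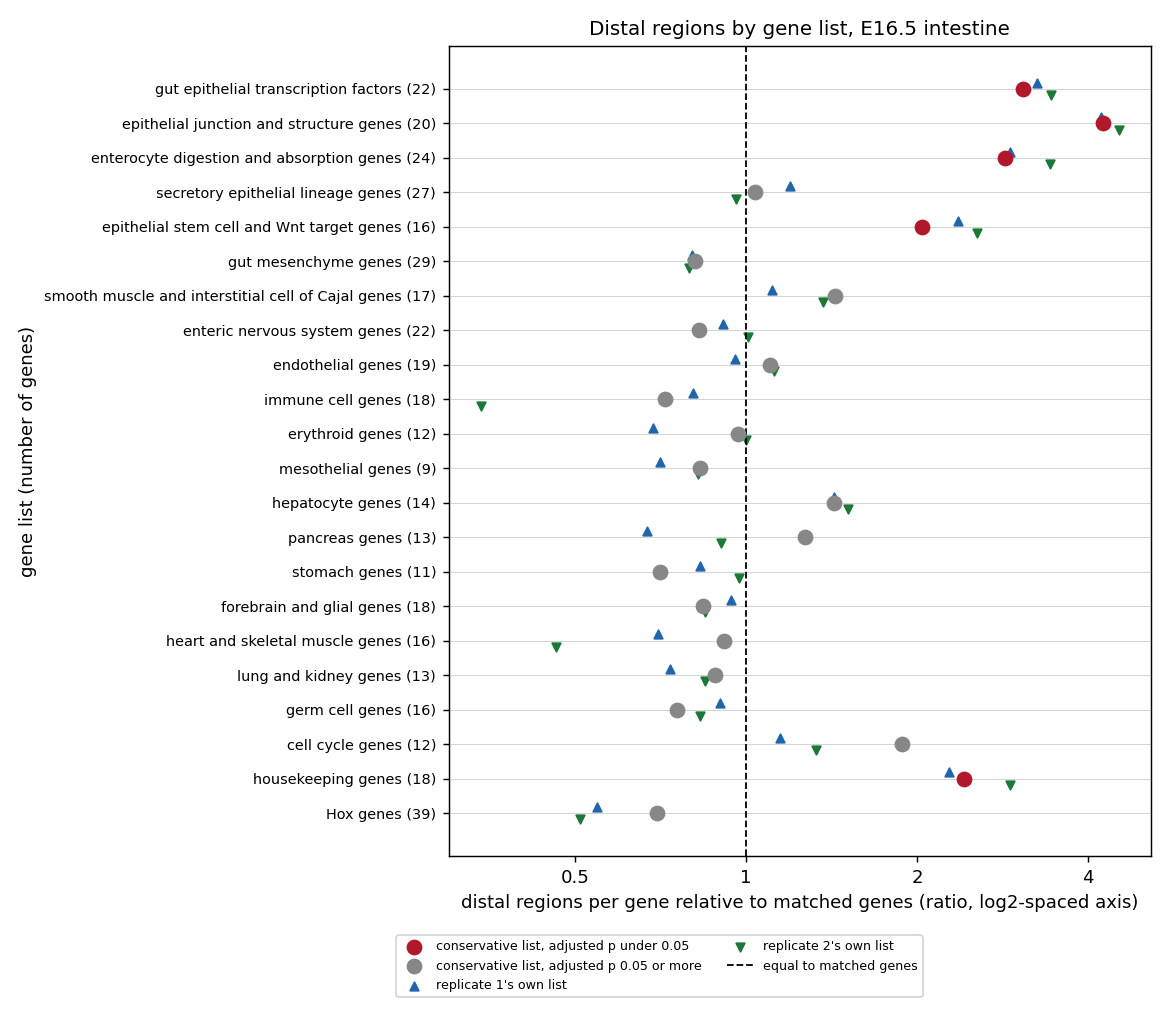
Mean number of distal regions per gene, as a ratio to random genes matched on territory (log2-spaced axis), for the 22 gene lists in the conservative list (circles, red when the adjusted p was under 0.05) and in the own list of each replicate (triangles). The dashed line marks a ratio of 1, with the 3 lists of epithelial transcription factors, junction genes and enterocyte genes between 2.86 and 4.26.

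The 10 distal regions with the highest signal value lay mostly in intergenic sequence. The strongest was on the X chromosome (143482936 to 143483180), 35532 bp from the start site of Pak3, with a mean signal value of 52.3 ± 1.20 (SD, n = 2), followed by a region on chromosome 2 (69355469 to 69355735), 12986 bp from Abcb11, with 51.4 ± 0.972. Regions nearest to G6pd2 (43.8 ± 0.304), Gm5426 (41.9 ± 0.195), Frmd4a (30.1 ± 0.244), Galc (29.3 ± 0.590) and Nxph1 (28.1 ± 1.98) came next, then regions in an intron of Gphn (26.9 ± 0.346), in the non-coding RNA gene Gm26561 near Myl12b (26.5 ± 2.84) and in an exon of Lars2 (26.4 ± 0.601). Of these 10, 4 matched mitochondrial DNA over 50% or more of their length, namely those nearest to G6pd2, Gm5426, Galc and Nxph1, and the region near Abcb11 matched over 48.3%. The distances to the nearest start site of G6pd2 and Galc were 1765838 bp and 1154985 bp.

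Motifs of intestinal epithelial factors were enriched at distal summits. The HNF4 consensus CAAAGTYCA occurred within 100 bp of 4.96% of 27566 distal summits against 0.564% of flanking windows (log2 ratio 3.13, 95% interval 2.96 to 3.32, adjusted exact p = 1.69e-249). The GATA consensus AGATAAG occurred at 9.45% against 2.87% (1.72, 1.63 to 1.80, adjusted exact p = 3.79e-241), KLF/SP at 8.51% against 1.35% (2.65, 2.53 to 2.76) and the CDX consensus TTTATKRY at 12.8% against 8.08% (0.67, 0.61 to 0.73, adjusted exact p = 7.62e-81). The HNF1 consensus was found at 0.0907% of summits and in no flanking window (adjusted exact p = 9.17e-08). The insulator factor motif CTCF had a ratio of 4.24 (3.95 to 4.59), at 2.92% of summits, and NFI had 3.68, both enriched. CTCF was 3.54 in the replicate 2 list alone and 3.98 in the replicate 1 list alone, where NFI was 4.03 and 4.52, so their order changed with the list. GRHL (2.03), AP-1 (1.62), the MYOD E-box (1.15), TEAD (0.87), the FOXA/FOXF forkhead motif (0.64) and TCF/LEF (0.62) were also enriched. PHOX2, a motif of enteric neurons, was depleted, at 0.0109% of summits against 0.0852% of flanks (−2.78, −5.52 to −1.54, adjusted exact p = 7.03e-05). In the own list of each library no summit held PHOX2, so that the ratios there were set by the 0.5 added to each count. The ratios of the CArG box bound by SRF (0.10), ETS (0.60), SOX (−0.24), RUNX (0.09), POU (−0.26) and REST (2.5) were not past the threshold, although ETS passed in 5 of 8 alternatives, SOX in 4, REST in 3, CArG in 2 and RUNX and POU in 1 each. The REST ratio was 1.22 in the replicate 1 list alone and 0.58 in the replicate 2 list alone. Against random distal positions matched on GC, the log2 ratio was 1.54 for CDX (12.8% against 4.40%), 1.97 for KLF/SP, 3.55 for HNF4 and 2.20 for GATA. For PHOX2 it was −1.89 (95% interval −4.70 to −0.68, 0.0109% against 0.0453%), nearer to no difference than against the flanks. The PHOX2 ratios rest on few matches, and their size is uncertain. In the own lists of the libraries the log2 ratio was 3.27 ± 0.08 for HNF4, 1.80 ± 0.09 for GATA and 0.76 ± 0.01 for CDX (SD, n = 2). Of 20 motifs, 13 were enriched and 1 depleted in exact McNemar tests. A consensus match is a sequence count and not a measurement of binding, and related factors share a consensus.

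**Figure D4:**
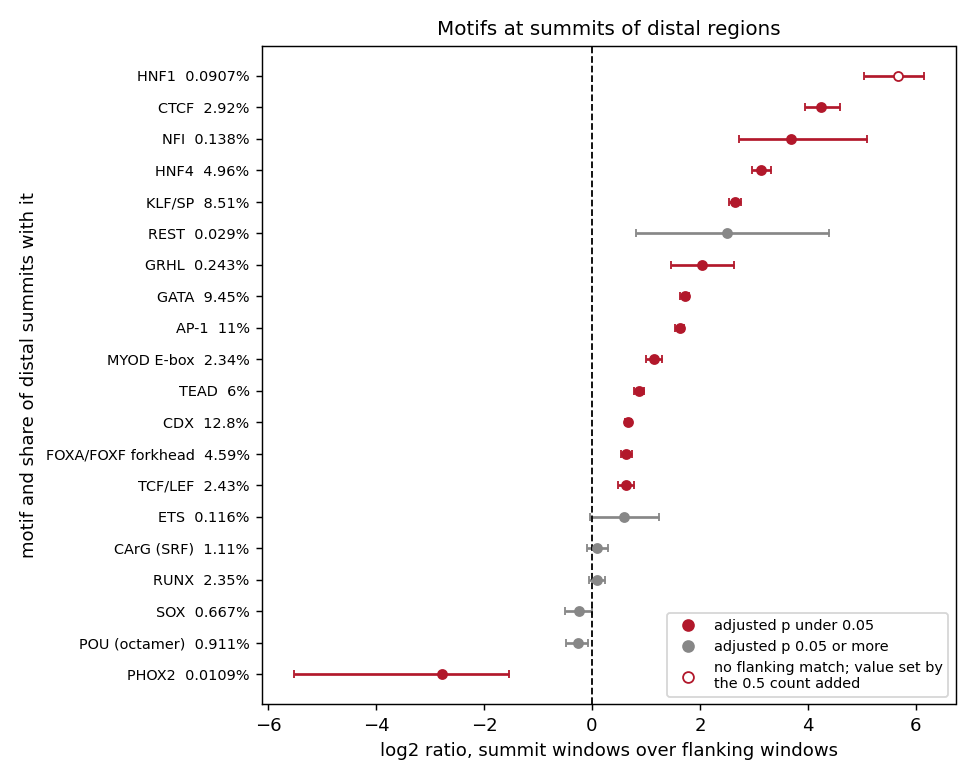
Log2 ratio of the share of distal summits with each of 20 motif consensus sequences to the share of flanking windows, with bars for the 95% bootstrap interval, red when the adjusted p was under 0.05. The percent of the 27566 summits with a match stands beside each name, and the open circle marks HNF1, which had no flanking match, so that its position is set by the 0.5 added to each count.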

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

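Both tests of the summits described here were chosen after these summits had been found.

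A set of summits, some of them strong, passed the authors' irreproducible discovery rate threshold in the ranked lists and was absent from the thresholded lists on which the report rests, so it is signal in data that no comparison above used. For both libraries together 109800 summits passed in the ranked list and 109550 were in the conservative list, which left out 250. The count left out was 200 in replicate 1 and 197 in replicate 2. Of the 250, 81 lay outside the chromosomes used here, on sequences that were not told apart, and the rest formed 66 regions on chromosomes. Their highest signal value was 49.5, against 54.8 among the summits kept, and their median was 6.27 in all and 7.92 on chromosomes, against a median of 6.46 over the conservative regions.

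The pattern weighed was this loss of summits. The conservative list held 0 summits outside the chromosomes used here, against 191 in the ranked list before thresholding. The loss of the 81 was therefore part of the absence of all such summits. The sequences of the 81 were not searched, and the searches for copies cover the 66 regions on chromosomes. Mitochondrial DNA copied into the nuclear genome is argued against as the source of these 66 regions. Of the 66, 1 (1.52%) matched mitochondrial DNA over 50% or more of its length. Near-identical copies elsewhere in the chromosomes were found for 15 of the 66 (22.7%), against 1 of 100 random distal regions. Copies may therefore account for a part of the 66 regions, and the share leaves copies open as their source. The thresholded lists were derived with a further set of regions, per the deposited notes, and removal by that set could not be tested because its content was not at hand. No biological explanation was tested.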

How the results depend on the processing

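Matching on GC content was chosen only after the distal results were seen, and all other alternatives were planned. Of the values that answer a comparison, 86 were unchanged and 21 moved. Unchanged meant the same side and call, or a value within the interval of the main one. For counts of lists, motifs or named genes, it meant a count within a fixed fold limit of the main count. A count could therefore lose a call and still be unchanged. Of the other values, which cover single lists, motifs and classes, the Jaccard index and Spearman's rho, 465 were the same, 44 changed direction, 36 lost and 33 gained a call, and 7, all of the Jaccard index or rho, moved. No list or motif that changed direction was past the threshold under the alternative. The cause was not tested for any change below.

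Pearson's r was 0.951 with −log10 p, 0.916 in the pseudoreplicated lists, 0.929 without the strongest 1% of regions, 0.954 at promoters and 0.888 at distal regions. With 50% of both regions required, 91.2% of replicate 1 and 92.7% of replicate 2 regions were in the conservative list. In the replicated list the exon share (3.97%, permutation p = 0.0198) moved above chance, and the intron share (40.3%, permutation p = 0.515) was no longer below it past the threshold.

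Promoters of junction genes stayed above and those of germ cell genes below other genes in all 9 alternatives (85.0% to 100% and 12.5% to 31.3%). Other list calls were lost or gained, and 3 lists (junction, cell cycle and housekeeping) were above with only the 5' end of each gene, where the transcription factor call ended (81.8%, adjusted p = 0.0814, Fisher's exact test; 81.8% to 100% over the alternatives), while 2 were below in the replicated list and 3 with a 2 kb window. Of the named genes without a promoter region, 17 had none in the replicated list.

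Shares that crossed to the other side of their comparison genes were, in the replicated list, enteric nervous system 77.3%, pancreas 84.6%, forebrain 94.4% and Hox genes 76.9%. In the optimal list the endothelial share did so (63.2%). Without replicate 1 they were mesenchyme 58.6%, endothelial 36.8%, erythroid 41.7% and mesothelial 44.4%. Without replicate 2 they were endothelial 42.1% and erythroid 41.7%, while mesenchyme (72.4%) and mesothelial (77.8%) did not cross. With a 500 bp window they were erythroid 58.3% and mesothelial 44.4%, and with only the 5' end enterocyte 58.3%, endothelial 52.6% and mesothelial 55.6%. Matched on CpG content, the pancreas share of 53.8% was above its matched genes.

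Distal regions at gut epithelial transcription factors, junction genes and enterocyte genes stayed above matched genes in all 9 alternatives, with ratios of 2.18 to 4.67, 2.94 to 5.01 and 2.26 to 3.44. The number of lists above was 3 with −log10 q of at least 10, 3 within 50 kb and 3 with GC matching, and 1 list, Hox genes, was below with no matching (ratio 0.212). Ratios that crossed 1 were, in the optimal list, secretory 0.976 and heart 1.09, and in the replicated list secretory 0.977, mesenchyme 1.16, mesothelial 1.02 and Hox genes 1.38. Without replicate 1 they were secretory 0.960, enteric nervous system 1.01, erythroid 1.00 and pancreas 0.902, and without replicate 2 endothelial 0.956 and pancreas 0.671. With the other replicate left out, those that crossed in 1 of the 2 were secretory 1.20, enteric nervous system 0.911, erythroid 0.686 and endothelial 1.12. Within 50 kb they were erythroid 1.07 and lung and kidney 1.23, and within 500 kb secretory 0.923, mesenchyme 1.1 and erythroid 1.01. With no matching they were mesenchyme 1.52, enteric nervous system 1.09, mesothelial 1.03 and forebrain 1.18, and with GC matching secretory 0.942, endothelial 0.799 and erythroid 1.30.

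The 14 motif calls were kept in all 8 alternatives. Enrichment calls were gained for ETS in 5, among them without replicate 1 (log2 ratio 1.08) and more distant flanks (1.56), REST in 3, CArG in 2 and RUNX in 1. The number of depleted motifs was 3 in the replicated list (PHOX2, SOX and POU), 2 with more distant flanks and 2 against random positions matched on GC (PHOX2 and SOX in both), and 1 to 2 with a replicate left out, where SOX was added without replicate 2 (log2 ratio −0.31). The POU log2 ratio was 0.00863 against the random positions. The lists outside the central 95% of the replicate ratio numbered 4 with −log10 p and 1, gut epithelial transcription factors, with promoter regions only.

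What depth limits could not be examined, since the deposited lists hold no counts.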

Other observations

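The genes, motif comparisons and groups by strength in this part, and the tests of both patterns, were chosen only after the results above were seen.

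The gene with the most distal accessible regions was Pde4d. This cyclic AMP phosphodiesterase gene on chromosome 13 had 27 within 100000 bp, Nav2 25, Gse1 23, Arhgap26 22 and the ubiquitin ligase gene Nedd4l 21. Per unit of assignable genome Gse1 was denser, with its 23 regions in 316 kb against 27 in 1565 kb for Pde4d. The Wnt effector gene Tcf7l2 had 17, and Myo5b, a motor of apical transport, had 16. Of these 7 genes all had an accessible promoter, and Megf11, with 17 distal regions, did not.

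Region strength went along with different sequence. In 10 equal groups of the conservative regions by rising signal value, the promoter share ran from 20.6% in group 2 to 80.9% in group 10. The HNF4 motif was at 3.73% of distal summits in group 1 and 7.09% in group 10, and GATA at 7.51% and 10.5%, with its highest share in group 9 (12.4%). CTCF was at 3.13% in group 1, 3.83% in group 4 and 1.30% in group 10. AP-1 was at 9.71% (8.73% to 10.8%) in group 1 and had its highest share in group 9 (13.7%, 12.2% to 15.5%), where the interval lay above that of group 1. In group 10 it was at 11.3% (9.38% to 13.7%), with an interval that overlapped that of group 1.

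At the 345 distal regions of the 4 gut epithelial lists, 1 held the CTCF consensus (0.290%), against 2.95% of the other distal regions (adjusted p = 0.0192, Fisher's exact test). CDX (17.7% against 12.8%) and AP-1 (15.7% against 11%) were more frequent there without passing the correction over 20 motifs (both adjusted exact p = 0.0619). At 146 distal regions of mesenchyme, smooth muscle, enteric nervous system and endothelial genes the CTCF share was 4.11% (adjusted p = 0.835, Fisher's exact test). These tests count regions of the same gene as independent, and the other distal regions include those not assigned to any gene.

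The strongest distal regions formed a pattern of short intervals with signal values up to 52.3 (mean of the libraries). Near-identical copies elsewhere in the chromosomes were found for 1 of the 10, the region nearest to G6pd2, against 1 of 100 random distal regions. By the limit set before the test, a count of 1 went against such copies as the source. Copies outside the assembled chromosomes could not be counted in this search. The search therefore cannot decide, and sequence present in several near-identical copies stays open as the source. Mitochondrial sequence copied into the nuclear genome matched 4 of the 10 over 50% or more of their length, against 0 of 100 random distal regions, and may lie behind those 4, but 5 had no match and the source of the 10 as a set stays open. No biological explanation was tested.

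The other pattern weighed was the distal excess at the transcription factor, junction, enterocyte and stem cell lists, pooled because each was already called, and without the secretory lineage list, which had no excess (ratio 1.04, and 0.942 with GC matching). The pooled ratio was 2.88 with matching on territory and 2.18 with GC matching in addition. The pooled lists were chosen by their own result, so the pooled ratio cannot decide on GC content of the surroundings. List by list with GC matching, the ratio was 2.18 for transcription factor, 3.55 for junction and 2.93 for enterocyte genes (each adjusted permutation p = 0.00147). These values argue against GC content as the whole cause for these lists. The stem cell list lost its call (1.31, adjusted permutation p = 0.497), so GC content stays open there. A threshold that keeps elements of the most abundant cells is left open. The regions added by the looser list had a ratio of 1.33 at mesenchyme, smooth muscle, enteric nervous system and endothelial genes (permutation p = 0.0226). In the conservative list that ratio was 0.987. At the 4 lists the added regions had a ratio of 1.95, against 2.88 in the conservative list. The rise goes with such a threshold. The fall can also come from the choice of the 4 lists by their result in the conservative list. The 4 lists stayed higher in the added regions, by more than the margin set before this test as counting against such a threshold. The looser list is also thresholded and from the same tissue, so the test cannot decide. Elements bound by HNF4 stay open, with the motif at 12 of the 345 regions (3.48%, 95% interval 2.00% to 5.98%) against 4.97% of the others (p = 0.259, Fisher's exact test). The value alone went against HNF4, and the requirement that the interval exclude the share of the others was set after the value was seen.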
